A study of Homo sapiens with 4 samples.

How the data were processed

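Total RNA of HEK293 cells, a human line derived from embryonic kidney, was profiled on 4 single-channel Affymetrix expression arrays after biotin labelling of cRNA, per the labels' protocols. Cells kept in culture gave 2 arrays, and cell pellets recovered from immunodeficient NOD.Scid mice gave 2 arrays. Groups were taken from the sample titles. The labels call the samples of a group biological replicates without saying whether they came from separate cultures or animals. P-values of single genes therefore measure no more than the spread between these samples.

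The deposited table held 1 linear array intensity per probe set and array for 54675 probe sets. GCOS was used according to the submitters' processing notes, and its version and settings are not given in the sources used here. The deposited intensities had the same mean on each array after trimming 2% of probe sets at either end (200.02 on all 4 arrays), which is what scaling each array to a common target gives. By a rule fixed before the data were examined, the deposited scaling was therefore kept. Detection calls, scan dates and probe sequences were not used here. Scaling to a common mean removes any change in total RNA per cell, and every difference is relative to the other probe sets of the array.

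Probe sets were named through the platform annotation given with the table. One gene symbol was attached to 41097 probe sets, several to 1801 and none to 11777; genes without a named probe set were not analysed here. Entrez identifiers of 41043 probe sets matched the current human gene table of assembly GRCh38.p14, which was used only for names and for the order of neighbouring genes. The 62 Affymetrix control probe sets were left out of the tests. A probe set was kept where its mean over the 4 arrays was at least the median of all probe sets (31.3 signal units), and each gene was represented by its kept probe set with the highest mean. This left 12547 genes.

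Values were analysed as log2(signal + 16), which understates changes of dim genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with no replicate block and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Differences are in vivo minus in vitro, and SDs are over the 2 arrays of a group on the signal scale. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so significance rests on the spread that limma shares between genes. Gene lists were fixed beforehand too: 45 lists, of which 37 had at least 5 tested genes. They were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera at the preset correlation sets the members of a list against the other genes. Its p-values rest on the spread between genes and do not measure the spread between samples. The genes named are the 12 largest called rises and the 12 largest called falls whose arrays did not overlap between groups, and up to 4 members with the smallest p of each list described; for lists of other cell types, also the 3 members with the highest in vivo signal. Members beyond these were named after their values were seen.

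The tests were tried on simulated data with the arrays' own mean signals and with spreads drawn around the fitted trend, independent between genes. In each of 5 runs, 200 of 12547 simulated genes were changed. Of genes changed by 1 on the log2 scale 72.8% were recovered, and of those changed by 0.5, 36.4%. Of all calls 5.07% were false, and 5 simulations with no change gave 0 calls. Far fewer genes were changed than the 2015 called in the data, and these rates depend on that share. The same prior spread was used to simulate and to test, so these rates assume that the trend holds.

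Alternatives covered the pseudocount, the filter, quantile and median scaling, the choice of probe set, the variance prior, a replicate block and leaving out each array, and, added after the data were seen, cyclic loess normalization; an array left out leaves a group with 1 array, whose spread is then assumed to be that of the other group. Runs of neighbouring genes were sought after the data had been seen, as the stretch of at least 30 genes per chromosome that stood out most in replicate 1 of both groups, then measured in replicate 2; those whose median log2 difference in replicate 1 was below -0.2 were tested further. The search recovered 20 of 20 simulated stretches, which were lowered about as much as the strongest ones found. Weaker stretches, and chromosomes without any stretch, were not simulated. Intervals of medians over genes are bootstrap intervals, which resample genes as if independent and do not measure the spread between arrays. Figures were drawn with matplotlib 3.10.9.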

Results

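Gene expression was compared between HEK293 cells grown in culture medium with 450 mg/dl glucose and HEK293 cells expanded under the skin of NOD.Scid mice for 3 weeks. The comparison addressed which genes differ when the same human cell line grows in an animal rather than in a dish. Each condition was represented by 2 arrays. The number of arrays limits the precision. Across the 12547 genes tested, the correlation across genes was 0.991 between both in vitro arrays and 0.991 between both in vivo arrays, and lay between 0.980 and 0.981 across conditions; genes are not independent replicates. The median absolute log2 difference was 0.097 between the in vitro arrays, 0.094 between the in vivo arrays and 0.16 between the group means. The 3'/5' signal ratio of the GAPDH control, a measure of RNA integrity, was 1.01 on both in vitro arrays and 1.02 and 1.06 on the in vivo arrays. Transcripts spiked into the hybridization mix were brighter in vivo, with a median ratio of 1.31 over 18 control probe sets.

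Expansion in the mouse was accompanied by many small changes and few large ones. Of 12547 genes, 2015 passed the threshold, 912 higher and 1103 lower in vivo (limma, Benjamini-Hochberg adjusted p under 0.05). The median size of a called change was 1.3-fold, and 101 called genes differed at least 2-fold, 45 higher and 56 lower. In vivo and in vitro values did not overlap for 61.4% of all genes, against 33.3% expected by chance for 2 arrays against 2. With each array centred on its median instead, the split of higher and lower calls turned to 1240 and 845. Without in vitro replicate 1 or 2 the count fell to 873 or 971, and without in vivo replicate 1 or 2 to 959 or 774. A variance prior that ignored signal level left 86 calls.

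The largest rise at the pseudocount of 16 was that of IL13RA2, a decoy receptor for interleukin 13, with a signal of 9.24 ± 10.6 in vitro and 556 ± 27.2 in vivo (SD, n = 2; log2 difference 4.57 ± 0.28 SE, limma adjusted p = 0.0013). Its in vitro signal lay under the filter limit of 31.3, where signal cannot be told from background here, and its log2 difference was 6.32 with a pseudocount of 1 and 3.09 with 64. MAGEC2, a cancer-testis antigen normally restricted to germ cells, rose from 7.6 ± 4.14 to 106 ± 6.13 (log2 difference 2.38). Its in vitro signal also lay under the limit, and its log2 difference was 3.72 with a pseudocount of 1 and 1.25 with 64. TAGLN, an actin-binding protein of contractile cells, rose from 87.1 ± 14.7 to 455.5 ± 1.57, with 2 of its 3 tested probe sets called higher. PKP3, a desmosomal plaque protein, rose from 130.9 ± 9.73 to 553.6 ± 40.7. RASGEF1A, an exchange factor for Ras-family GTPases, rose from 164.9 ± 21.1 to 582.6 ± 13.2, and the cytokine IL32 from 141.8 ± 15.8 to 465.7 ± 22.3. CKM, the muscle creatine kinase, rose from 13.4 ± 8.21 to 93.4 ± 0.594. The teneurin TENM1, KHDC1L, the scavenger receptor gene CD163L1, the noncoding RNA LINC01234 and the uroplakin UPK2 completed the 12 largest rises, with log2 differences of 1.89, 1.88, 1.77, 1.61 and 1.60.

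EEF1AKMT1, a methyltransferase of elongation factor 1A, fell from 144.1 ± 11.5 to 4.36 ± 0.766 (log2 difference -2.97 ± 0.21 SE, limma adjusted p = 0.0019), to an in vivo signal under the same limit. Its log2 difference was -4.76 with a pseudocount of 1 and -1.61 with 64, where COL2A1 (-1.68) and EEF1A2 (-1.62) fell more. One group's mean lay under the limit for 15 of the 24 genes named by size of change, so their order depends on the pseudocount. EEF1AKMT1 lies within a run of 150 tested neighbours on chromosome 13 whose median log2 difference was -0.27 relative to all genes. The elongation factor EEF1A2 fell from 779.5 ± 3.88 to 210.6 ± 4.98, a 3.51-fold difference with an adjusted p of 0.00079. COL2A1, the chain of type II collagen, fell from 205.5 ± 1.77 to 20.3 ± 1.04, with both tested probe sets called lower. MYD88, the adaptor of Toll-like and interleukin 1 receptors, fell from 235.6 ± 22 to 55.5 ± 9.97, and the atypical cadherin FAT3 from 279.8 ± 7.22 to 66.3 ± 6.14, with 1 of its 3 probe sets called. The transcription regulator TOX3, TMEM42, the tetraspanin CD82, KRABD1, the homeobox gene PRRX2, the inositol trisphosphate receptor ITPR3 and GARIN5A had log2 differences of -2.54, -2.06, -1.93, -1.88, -1.81, -1.80 and -1.73. PRRX2 lies in a run of 60 neighbours on chromosome 9 with a median of -0.29. Of these 24 genes, 18 passed in all 4 fits without 1 array; PRRX2 and TOX3 passed in the 2 and 3 fits that kept them above the signal filter. CD163L1 did not pass without in vivo replicate 1 or 2 (limma adjusted p = 0.0793 and 0.0662), UPK2 without in vitro replicate 2 or in vivo replicate 2 (0.0516 and 0.0738). ITPR3 did not pass without in vitro replicate 1 or 2 (0.0805 and 0.0611) and GARIN5A without in vitro replicate 1 (0.0719). CD163L1 and ITPR3 also did not pass with no filter on low values (0.0551 and 0.05). With the mean of a gene's probe sets, the log2 differences shrank from 2.20 to 1.35 for TAGLN, from -1.93 to -1.07 for CD82 and from -1.85 to -1.02 for FAT3. Without the trend in the variance prior, 14 of the 24 passed.

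**Figure D1:**
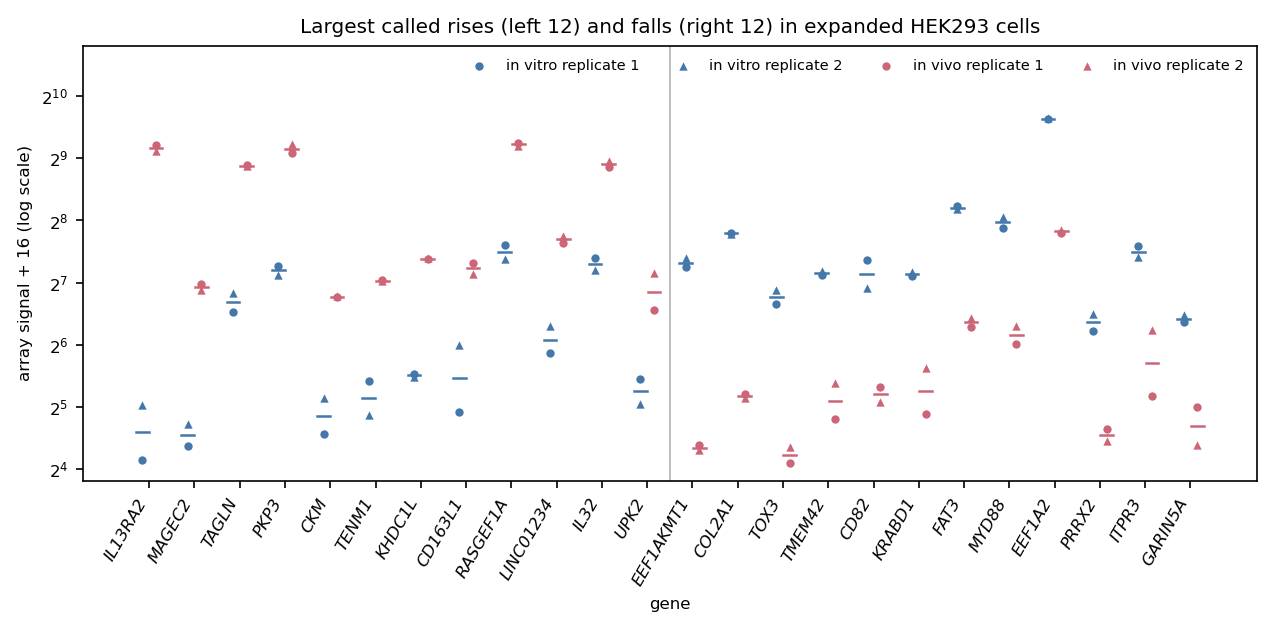
Array signal plus 16 on a log2-spaced axis for the 12 largest called rises (left of the grey line) and the 12 largest called falls (right), with 1 point per array (circles replicate 1, triangles replicate 2; blue in vitro, red in vivo) and a bar at the mean of the log values. IL13RA2 moved from a mean signal of 9.24 to 556 and EEF1AKMT1 from 144.1 to 4.36. The genes were chosen so that in vivo and in vitro points do not overlap.

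Of the 37 gene lists tested, 8 passed the set test against all other genes (camera at a preset correlation of 0.01, adjusted p under 0.05), 5 higher and 3 lower in vivo. None of the 8 passed with a correlation estimated from these 4 arrays, which leaves that test few degrees of freedom: the lowest adjusted p was then 0.592. All 8 passed fry, which asks whether the genes of a list move one way and does not compare them with other genes. Fry passed 18 lists in all. Single members rest on the trend in the variance prior more than the 24 genes above: without it, 2 of the 31 further members with the smallest p of these 8 lists passed, CCN2 and KRT19. Of the 54 other called genes named, 11 passed without the trend. Some of the genes named below went the way of the median of the stretch of neighbouring genes that stood out most on their chromosome. PRIM1, KRT8 and DDIT3 lie in a stretch of chromosome 12 with median log2 differences of -0.14 and -0.16 in replicates 1 and 2. GPI, GYS1 and DNAJB1 lie in one of chromosome 19 with medians of -0.11 and -0.12. CYC1 and NEFL lie in one of chromosome 8 (-0.08 and -0.09), CCNA2 and ENPEP in one of chromosome 4 (0.13 and 0.12), and ATP6AP2 in one of chromosome X (0.14 and 0.14). ID1 lies in a raised stretch of chromosome 20 (0.16 and 0.09), CCN1 in one of chromosome 1 (0.10 and 0.10), DNAJB11 in one of chromosome 3 (0.09 and 0.07), and COL6A1 in a lowered one of chromosome 21 (-0.09 and -0.10). Medians were smaller in the stretch of chromosome 14 that holds ERO1A (0.07 and 0.08) and in that of chromosome 15 with TPM1, BUB1B and THBS1 (0.06 and 0.06). The stretch of chromosome 17 with KRT19, JUP and COL1A1 had -0.03 and -0.02. It spans 695 of the 769 tested genes there, with 53 called lower and 32 higher. That of chromosome 8 spans 415 of 447 (62 lower, 9 higher). Neither singles out a part of its chromosome.

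Genes of the unfolded protein response, which help proteins fold in the endoplasmic reticulum, rose together. Of 19 tested members 12 rose and none fell, with a median log2 difference of 0.38 over all members (camera adjusted p = 5.28e-08; adjusted p = 0.592 with an estimated correlation). Adjusted over the list alone, 15 rose and none fell. The co-chaperone DNAJB11 rose from 1592 ± 89.9 to 2452 ± 27.3, a 1.54-fold difference with a limma adjusted p of 0.0028. HSPA5, the main luminal chaperone, rose from 3908 ± 121 to 5378 ± 165. HSP90B1 rose from 1549 ± 24.1 to 2157 ± 25.2 and the disulfide isomerase PDIA4 from 1374 ± 5.11 to 1889 ± 43.5. Among heat shock chaperones of the cytosol and mitochondria, 6 of 11 tested members rose and 1 fell, with a median of 0.18 (camera adjusted p = 0.0053; adjusted p = 0.592 with an estimated correlation). In all, 7 rose and 1 fell when adjusted over the list alone. STIP1 rose from 4827 ± 92.2 to 5862 ± 100.5 and HSPD1 from 10090 ± 98.5 to 11600 ± 333. DNAJB1 fell from 1645 ± 0.438 to 1356 ± 66. With the mean of its probe sets, HSPD1 did not pass (log2 difference 0.12 against 0.20, limma adjusted p = 0.275). DNAJB1 did not pass without in vitro replicate 1, in vitro replicate 2 or in vivo replicate 1 (0.0689, 0.066 and 0.0802).

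Genes of the actin cytoskeleton, many of them targets of serum response factor, were higher in vivo as a list: 7 of 17 rose and 1 fell, with a median of 0.19 (camera adjusted p = 0.0037; adjusted p = 0.592 with an estimated correlation). Adjusted over the list alone, 9 rose and 2 fell. The median of this list was 0.09 without in vitro replicate 2, 0.13 without in vivo replicate 1, 0.12 with a pseudocount of 64 and 0.11 with the mean of a gene's probe sets, and the list passed in each case (range of camera adjusted p over all alternatives 0.000277 to 0.0181). Besides TAGLN, tropomyosin TPM1 rose from 2208 ± 130 to 2838 ± 8.32 and the focal adhesion protein ZYX from 728.3 ± 19.4 to 936.7 ± 13.5. Smooth muscle actin ACTA2 fell from 1213 ± 21.1 to 892.4 ± 66.4. Of 12 tested targets of transforming growth factor beta, 5 rose and none fell, with a median of 0.26 (camera adjusted p = 0.0050; adjusted p = 0.592 with an estimated correlation). In all, 7 rose when adjusted over the list alone. CCN2, a matricellular growth factor, rose 2.97-fold from 614.9 ± 21.6 to 1857 ± 12.6 (limma adjusted p = 0.00070), and TGFB2 itself from 58.6 ± 18.9 to 129.7 ± 21.9. ID1 rose from 2843 ± 55.5 to 3717 ± 28.6, and ID3 from 2167 ± 30.1 to 2548 ± 50.3. TGFB2 did not pass without in vitro replicate 2, in vivo replicate 1 or in vivo replicate 2 (limma adjusted p = 0.0902, 0.124 and 0.064), nor with no filter on low values (0.0815) or the mean of its probe sets (log2 difference 0.59 against 0.98, 0.0786). ID3 did not pass without in vitro replicate 1, in vivo replicate 1 or in vivo replicate 2 (0.0584, 0.0501 and 0.0762), and ZYX did not pass without in vitro replicate 2 or in vivo replicate 2 (0.0508 and 0.06).

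Genes of DNA replication and the G1/S transition were lower in vivo. Of 26 tested members 8 fell and none rose, with a median of -0.11 (camera adjusted p = 0.0053; adjusted p = 0.592 with an estimated correlation). Adjusted over the list alone, 11 fell and 1 rose. With each array centred on its median the list's median was -0.06 (camera adjusted p = 0.0338; range over all alternatives 0.00024 to 0.0481). The helicase subunits MCM5 and MCM7 fell from 3382 ± 74.3 to 2645 ± 73.4 and from 5117 ± 145 to 4409 ± 97.6, and the primase PRIM1 from 956.0 ± 29.6 to 733.7 ± 12.1. RFC3 also fell, with a log2 difference of -0.36; it lies in the chromosome 13 run named above, and with the mean of its probe sets its log2 difference was -0.14 and did not pass (limma adjusted p = 0.209). MCM7 did not pass without in vitro replicate 2 or in vivo replicate 2 (limma adjusted p = 0.051 and 0.0683), nor PRIM1 without in vitro replicate 2 (0.05). Mitotic genes did not pass as a list: of 28, 2 rose, 1 fell and 25 did not pass, with a median of -0.02 and a mean of 0.01 (camera adjusted p = 0.714, direction up); the counts were the same adjusted over the list alone. Cyclin A2 (CCNA2) rose from 1101 ± 8.13 to 1422 ± 3.05, UBE2C fell from 3338 ± 48 to 2469 ± 226, and BUB1B rose from 1719 ± 50.7 to 2027 ± 48.8. BUB1B did not pass without in vitro replicate 1, in vivo replicate 1 or in vivo replicate 2 (limma adjusted p = 0.0813, 0.0601 and 0.098). PLK1 had signals of 1245 ± 5.23 and 1400 ± 9.67 (adjusted p = 0.057, limma).

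Oxidative phosphorylation genes fell by small amounts: 9 of 23 fell and 1 rose, with a median of -0.10 (camera adjusted p = 0.0060; adjusted p = 0.592 with an estimated correlation). In all, 12 fell and 2 rose when adjusted over the list alone. UQCRC2 of complex III fell from 2456 ± 62 to 1946 ± 10.3, CYC1 from 4653 ± 34.5 to 3991 ± 2.89 and NDUFA1 from 7175 ± 220 to 6204 ± 62.5. With the mean of its probe sets, the log2 difference of UQCRC2 was -0.15 against -0.33 (limma adjusted p = 0.0424). Centring each array on its median ended the call of this list, with a median of -0.05 (camera adjusted p = 0.0935; range over all alternatives 0.00103 to 0.139). NDUFA1 did not pass without in vivo replicate 2 (limma adjusted p = 0.0562). Ribosome biogenesis genes went the other way: 6 of 17 rose and none fell, with a median of 0.13 (camera adjusted p = 0.012; adjusted p = 0.65 with an estimated correlation). Adjusted over the list alone, 7 rose and 1 fell. MRTO4 rose from 765.3 ± 75.2 to 1155 ± 86.2, nucleolin (NCL) from 5392 ± 87.5 to 6068 ± 85 and RRP12 from 201.0 ± 9.77 to 296.4 ± 16. Without in vitro replicate 2 the list no longer passed (camera adjusted p = 0.0746; range over all alternatives 0.0022 to 0.0746). NCL did not pass without in vitro replicate 1, in vivo replicate 1 or in vivo replicate 2 (limma adjusted p = 0.0584, 0.0558 and 0.084). RRP12 did not pass without in vitro replicate 2 or in vivo replicate 2 (0.0653 and 0.0754).

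Of 10 tested epithelial adhesion genes 5 fell and none rose, with a median of -0.20 (camera adjusted p = 0.045; adjusted p = 0.68 with an estimated correlation). In all, 6 fell and 1 rose when adjusted over the list alone. These counts cover the list only: the desmosomal plaque gene PKP3, not among the tested members, rose 3.88-fold. Keratin 19 (KRT19) fell 2.37-fold, from 1309 ± 48.5 to 543.4 ± 7.64. P-cadherin (CDH3) fell from 233.0 ± 76.4 to 65.9 ± 21.2, plakoglobin (JUP) from 898.4 ± 27.3 to 599.1 ± 13.4 and keratin 8 (KRT8) from 6337 ± 68.8 to 5461 ± 89. The list did not pass without in vitro replicate 2 (camera adjusted p = 0.0628), without in vivo replicate 2 (0.0846) or in 4 further settings (range over all alternatives 0.0086 to 0.877). CDH3 did not pass without in vitro replicate 1 (limma adjusted p = 0.0508).

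**Figure D2:**
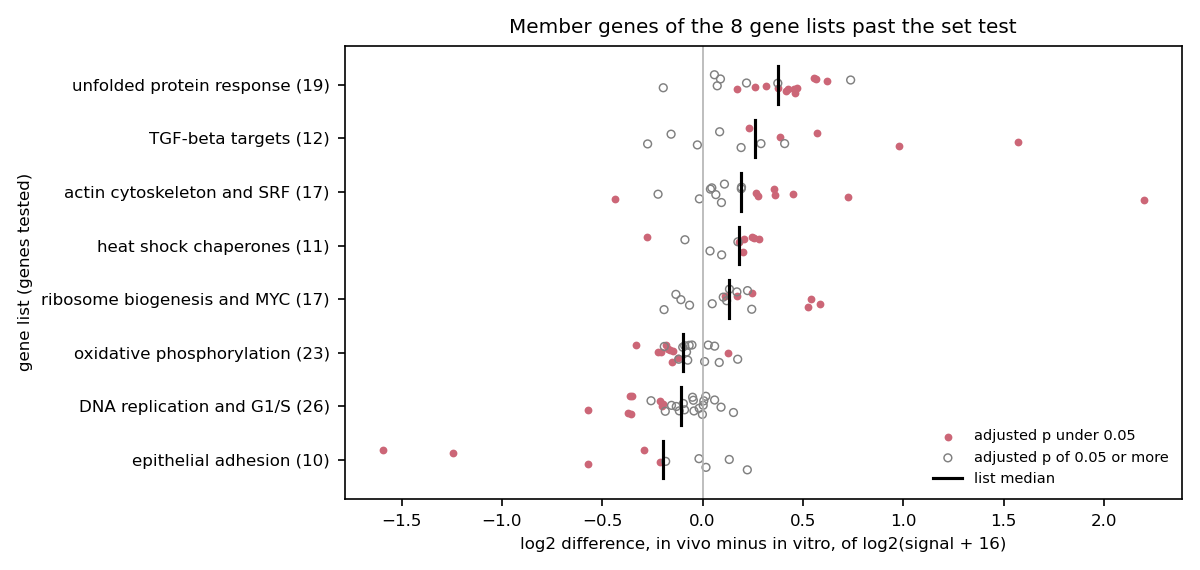
Log2 difference (in vivo minus in vitro, of signal plus 16) of every tested member of the 8 gene lists that passed the set test, 1 point per gene (filled, adjusted p under 0.05; open, 0.05 or more) and a black bar at each list's median. The medians run from 0.38 for the unfolded protein response to -0.20 for epithelial adhesion, and single members such as TAGLN at 2.20 lie far beyond their list's median.

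Genes of glucose uptake and the response to carbohydrate changed in both directions: 3 of 14 rose, 3 fell, and the list as a whole did not pass (median -0.02, camera adjusted p = 0.872; the same counts adjusted over the list alone). TXNIP, an arrestin-like protein induced by glucose, fell 2.56-fold, from 1135 ± 21.1 to 434.3 ± 4.05 (limma adjusted p = 0.00079), and its relative ARRDC4 fell from 462.8 ± 20.6 to 240.7 ± 7.28. The glucose transporter SLC2A3 rose from 949.1 ± 16.1 to 1726 ± 8.32, and glycogen synthase GYS1 fell from 1523 ± 81.6 to 1089 ± 68.5. Of 16 glycolytic genes 1 rose and 4 fell, among them GPI from 3850 ± 63.4 to 3135 ± 34.8, and the list did not pass (camera adjusted p = 0.633; 2 rose and 6 fell adjusted over the list alone). Of 22 hypoxia genes 2 rose, 1 fell and 19 did not pass (camera adjusted p = 0.67; the same counts adjusted over the list alone). ERO1A rose from 816.2 ± 20.7 to 1081 ± 15.2 and MXI1 fell from 1046 ± 21.4 to 790.0 ± 10.4. Genes of amino acid starvation moved apart, with 5 of 21 higher and 7 lower. DDIT4, an inhibitor of mTORC1 signalling, fell from 2517 ± 23.5 to 1295 ± 32.2 and DDIT3, a stress transcription factor, from 278.8 ± 0.38 to 161 ± 3.27. MTHFD2 rose from 1542 ± 56.5 to 2094 ± 9.54 (camera adjusted p = 0.672 for the list; 6 rose and 7 fell adjusted over the list alone).

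Extracellular matrix genes also divided, with 7 of 23 higher and 4 lower (median 0.03, camera adjusted p = 0.762; 7 and 6 adjusted over the list alone). TIMP1 fell from 5969 ± 228 to 4268 ± 11.1 and fibronectin (FN1) from 2543 ± 38.9 to 1473 ± 122. COL6A1 fell from 1721 ± 10.2 to 1209 ± 7.19 on the probe set tested, but with the mean of its probe sets its log2 difference was -0.02 against -0.50 (limma adjusted p = 0.885). LAMA5 fell from 1068 ± 82.1 to 619.2 ± 36.6. The log2 difference of FN1 was -0.78, and it was -0.51 without in vitro replicate 1, -0.52 without in vitro replicate 2 and -0.50 with the mean of its probe sets. The 7 that rose, named after their values were seen, were COL12A1, THBS1, LAMA1, TIMP3, LAMC1, COL4A1 and TNC. THBS1 did not pass without in vivo replicate 1 or 2 (limma adjusted p = 0.0611 and 0.0501), nor LAMA1 and TIMP3 without in vitro replicate 1 (0.0508 and 0.0783) or in vivo replicate 2 (0.0603 and 0.107). LAMC1, COL4A1 and TNC did not pass without any 1 of the 4 arrays (limma adjusted p from 0.0593 to 0.125), nor LAMC1 and COL4A1 with the mean of a gene's probe sets (0.0688 and 0.115) or TNC with no filter on low values (0.0887). Immediate early genes showed 5 of 15 higher and 2 lower (median -0.03 and mean 0.04, camera adjusted p = 0.714, direction up; 5 and 5 adjusted over the list alone). JUN fell from 2559 ± 32.8 to 1306 ± 64.1 and CCN1 rose from 1256 ± 21.5 to 1694 ± 1.54. Of 12 neuronal genes above the signal filter 1 rose and 3 fell (camera adjusted p = 0.217; 1 and 4 adjusted over the list alone), among them the neurofilament NEFL, which fell from 2975 ± 42.4 to 1746 ± 34.3. Of 13 targets of p53, TP53I3 rose from 209.3 ± 15.8 to 539.4 ± 13.8. CDKN1A, the cell cycle inhibitor p21, fell from 2574 ± 66.8 to 1595 ± 78.9, and 3 fell in all (camera adjusted p = 0.424; 1 rose and 5 fell adjusted over the list alone). None of 10 NF-kappaB genes passed limma, over all genes or adjusted over the list alone. NFKBIA alone (1 of 10) had an unadjusted p under 0.05, with signals of 426.3 ± 11.5 and 503 ± 18.8 (limma adjusted p = 0.077). Of the renin-angiotensin and kinin system 3 genes were above the signal filter and none passed over all genes. Adjusted over the list alone ATP6AP2 and ENPEP were higher (limma adjusted p = 0.060 and 0.061 over all genes).

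Because a pellet recovered from a mouse can hold mouse cells, markers of fibroblasts, endothelium, macrophages and granulocytes, red cells, adipocytes, skeletal muscle and keratinocytes were read without the signal filter. Of 93 measured markers 2 rose and 3 fell, with a median log2 difference of -0.11 (limma over 19777 genes). Of these markers, 27 passed the signal filter of the main test, where 3 rose and 3 fell. Several of the brightest, among them PERP, SPARC and LOXL1, were about as bright in culture, where no mouse cells were present. SFN, which rose, and COL1A1, EGFL7 and CFD, which fell, also lay far above the filter limit in culture. Such markers say little about mouse RNA, and they enter the counts and the median. Among fibroblast markers with the highest in vivo signal, LOXL1 had 1724 ± 18.6 in vitro and 1599 ± 125 in vivo. SPARC had 1819 ± 131 and 1584 ± 6.92, and COL3A1 231.0 ± 27.1 and 322.5 ± 2.03. COL3A1 was called higher in the main test (limma adjusted p = 0.033) but not without the filter (0.067), nor in the main test without in vitro replicate 2, in vivo replicate 1 or in vivo replicate 2 (0.104, 0.0936 and 0.103). COL1A1 fell from 531.6 ± 61.9 to 308.9 ± 2.62, but did not pass with the mean of its probe sets (log2 difference -0.26 against -0.75, limma adjusted p = 0.0989). The endothelial gene EGFL7 fell from 512.9 ± 25.2 to 356.6 ± 34.6, a call that the main test did not make without in vitro replicate 2 or in vivo replicate 2 (limma adjusted p = 0.0714 and 0.0625). Also on the endothelial list, RGS5 had 60.4 ± 1.95 in vitro and 69.8 ± 13.8 in vivo. FLT1, which lies in the chromosome 13 run, had 68.7 ± 1.43 and 60.8 ± 7.32. The adipocyte gene CFD fell from 334.6 ± 8.24 to 210.6 ± 1.07, while LPL had 191.0 ± 1.41 and 155.2 ± 1.75 and PPARG 123.6 ± 24.4 and 129.5 ± 17.96. Of the red cell markers, CA1 had the highest in vivo signal, with 23.5 ± 21 and 53.3 ± 13.6 (limma adjusted p = 0.277). Beta-globin (HBB) had 42.4 ± 12.1 and 42.9 ± 33.9, and SLC4A1 had 37.2 ± 18 and 31.8 ± 29.1. CD74, the brightest macrophage marker in vivo, had 14.6 ± 16.3 and 47.6 ± 2.05 (adjusted p = 0.164), FCER1G 42.4 ± 4.45 and 40.8 ± 7.06, and CSF1R 19.6 ± 24.8 and 24.3 ± 12.1. Of the muscle genes brightest in vivo after CKM, TTN had 56.8 ± 0.435 and 50.3 ± 5.12, and ACTA1 26.4 ± 1.46 and 26.6 ± 6.01. Of the keratinocyte genes, PERP had 2974 ± 93.5 and 2950.0 ± 23.1, and KRT10 1208 ± 125 and 1437 ± 256. CKM rose with and without the filter, as did SFN, which encodes stratifin, from 556.2 ± 13.2 to 814.1 ± 9.996. How far these human probe sets bind mouse transcripts was not tested.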

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

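The tests of a trend with signal level, of RNA integrity, of mouse cells and of mouse muscle were chosen after part of their results had been seen.

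Spike controls of the hybridization mix, which enter no comparison of genes, stood apart between the groups. These are bacterial and phage transcripts (bioB, bioC, bioD and cre) added in fixed amounts. All 18 of their probe sets were brighter on both in vivo arrays than on both in vitro arrays, with a median ratio of 1.31 (range 1.15 to 1.44). The 6 probe sets of the dap poly-A control had a median ratio of 0.817, and 3 of them were dimmer on both in vivo arrays.

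A lower raw brightness of the in vivo arrays, raised by scaling, is a candidate explanation for the spikes and could also have produced gene calls, and the median log2 difference did climb with signal, from -0.070 among the 3137 dimmest genes (57 called higher, 101 lower) to 0.012 among the 3137 brightest (469 higher, 432 lower). The values argue against this trend, or a leftover difference in signal distribution, as the main source of the 2015 calls. Of these, 93.8% were still called with the same sign after quantile normalization. After cyclic loess normalization, which narrowed these medians to -0.031 and -0.001, 94% were. For the calls that were lost the trend stays open. An effect of raw brightness on single probe sets stays open for all calls. The arrays already had the same trimmed mean (200.02) and medians of 30.8 to 33.1, so both normalizations had little left to change. Degraded RNA is argued against by the 3'/5' signal ratio, whose in vivo over in vitro ratio was 0.97 for actin and 1.03 for GAPDH. The 3 possible splits of the 4 arrays are too few for a share under 0.05; the real split gave 2015 calls, the highest of the others gave 0, and 1 split, the real one, gave as many as 2015. Batch stays open, since no labelling or scan batches were used here, and if each group was labelled and scanned together, batch and group cannot be told apart.

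CKM, a skeletal muscle gene, rose by 1.92 on the log2 scale in cells taken from beneath the skin, where muscle RNA could have been carried along. Its in vitro signal of 13.4 lay under the filter limit, and its rise was 2.84 with a pseudocount of 1 and 1.03 with 64. The other 13 muscle genes had a median log2 difference of -0.14 (bootstrap interval -0.43 to 0.03), and all 93 markers of mouse cells had a median of -0.11 (-0.19 to -0.01). These medians do not decide whether RNA of mouse muscle, stroma or blood added to the rises. The median in vivo signal was 14.9 for the muscle genes and 14.4 for all markers, under the limit of 31.3, and single markers went both ways. How well human probe sets bind mouse transcripts was not tested, and a change of CKM within the human cells stays open too.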

How the results depend on the processing

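Leaving out the stretches of neighbouring genes and cyclic loess normalization were alternatives chosen after seeing the data; all others were fixed before. None of the 109 called genes and 8 lists followed through the settings reversed its direction. For genes, many settings could not show a reversal. Filters, variance priors and the replicate block leave a gene's log2 difference as it was (CD163L1 1.77 with no filter and without trend, AJUBA 0.27 with the block). The genes named by size of change were chosen for arrays that do not overlap. On the same probe set, another pseudocount or leaving out 1 array cannot reverse them. Among all called genes, 1143 had over 1 probe set tested. When every probe set was tested on its own, 326 of these had another called the same way and 12 had another called the other way. With the mean of a gene's probe sets, 1401 of the 2015 calls passed with the same sign (69.5%). The count of 2015 genes stayed within 1.5 times under pseudocounts of 1 and 64, the stricter filter, quantile and median scaling, cyclic loess (1961), the mean of a gene's probe sets, the robust prior, and without the stretches (1787). It moved to 1241 with no filter on low values (550 higher, 691 lower), where 19777 genes share the correction, and to 101 with a 2-fold minimum. With every probe set on its own, which counts probe sets rather than genes, 3027 of 27307 were called (1481 higher) and 11 lists passed. A variance prior without trend left 86 genes (30 higher, 56 lower), where the prior degrees of freedom fell from 4.28 to 1.87. All 86 were among the 2015. Leaving out 1 array gave 774 to 971 genes, 305 to 477 higher and 444 to 588 lower, of which 683 to 856 were shared with the main calls; these fits have fewer arrays and treat the lone array of a group as varying like the other group. The replicate block gave 2234 genes and 9 lists, and 1923 of the main calls kept their sign (of the 109 genes followed, AJUBA did not pass, limma adjusted p = 0.0518); same-numbered samples shared only a number, since their deviations did not go together (correlation across genes -0.006). Median centring moved the share of higher calls from 45.3% to 59.5%, with a shift of the median of all genes from -0.02 to 0.02. The 8 lists became 0 with an estimated correlation and 18 with fry, and 6 to 9 without 1 array. Epithelial adhesion was also lost with the stricter filter, the mean of probe sets, every probe set on its own (median then 0.04, against a test direction that stayed lower; adjusted p = 0.877) and no trend, and oxidative phosphorylation without trend (adjusted p = 0.139). For the settings without a stated reason the cause was not tested. With no detection calls, signals under the median of 31.3 cannot be told from background here, so folds and ranks of genes such as IL13RA2 (log2 difference 3.09 to 6.32) and EEF1AKMT1 (-4.76 to -1.61) depend on the pseudocount.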

Other observations

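The tests of the chromosome stretches that compare replicates, fit gene density or count genes below the median were chosen after the pattern had been seen; so were the bootstrap intervals that decide on the cancer-testis and YAP/TEAD genes. The other tests were noted as fixed before their results, on patterns noticed in the same data.

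Genes of protein turnover and of chromatin divided by member. Of 21 proteasome genes 6 rose and 2 fell (camera adjusted p = 0.503). Adjusted over the list alone, 7 rose and 3 fell. PSMA3 rose from 3453 ± 10.7 to 4111 ± 9.17 and PSMB7 fell from 5872 ± 53.2 to 4756 ± 65.4. With the mean of its probe sets PSMA3 had a larger log2 difference (0.39 against 0.25) but did not pass (limma adjusted p = 0.199). Of 14 histone and chromatin genes 2 rose and 4 fell (camera adjusted p = 0.71; 2 and 5 adjusted over the list alone): the chromatin protein HMGB2 rose from 5982 ± 166 to 7465 ± 276 and the histone variant H2AZ1 from 8413 ± 115 to 9667 ± 124, while the histone gene H2AC6 fell from 375.3 ± 5.87 to 225.3 ± 17.9. The long noncoding RNAs TUG1 and MALAT1 fell, from 3127 ± 242 to 2115 ± 75.8 and from 3311 ± 71 to 2722 ± 119 (limma adjusted p = 0.0051 and 0.013). The log2 difference of TUG1 was -0.37 against -0.56 with the mean of its probe sets. MALAT1 did not pass with the mean of its probe sets (limma adjusted p = 0.0621), without in vitro replicate 1 (0.0508) or without in vivo replicate 2 (0.0543). Of 14 kidney development genes 2 rose, WT1 and HOXD11, and 3 fell, SIX2, FOXD1 and BMP7 (camera adjusted p = 0.714; the same counts adjusted over the list alone). BMP7 was named after its value was seen. None of the 5 passed in every fit without 1 array. WT1 did not pass without in vitro replicate 1, in vitro replicate 2 or in vivo replicate 1 (limma adjusted p = 0.0755, 0.0599 and 0.083), HOXD11 without in vitro replicate 1 or either in vivo replicate (0.0645, 0.0694 and 0.0663). SIX2 did not pass without in vitro replicate 1 (0.0543), FOXD1 without in vitro replicate 2 or in vivo replicate 1 (0.0751 and 0.0754), and BMP7 without any 1 array (0.0518 to 0.115) or with no filter on low values (0.0528).

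Neighbouring genes moved together. Of 1033 overlapping windows of 100 neighbouring genes, 79 had a median beyond any of 1000 shuffles of gene order (shuffled medians from -0.14 to 0.13), and the most extreme was -0.286, on chromosome 7. Stretches were then sought in replicate 1 of both groups and measured in replicate 2. Chromosomes 7, 13 and 9 each held a stretch lower by more than 0.2 in replicate 1: 216 genes of chromosome 7 from FAM20C to CT66, 150 genes of chromosome 13 from MPHOSPH8 to KLF12 and 60 genes of chromosome 9 from TOR2A to ASS1. In replicate 2 their medians were -0.27, -0.34 and -0.26, and 160 of their 426 genes were called lower against 1 called higher. These 160 make up 14.5% of all genes called lower. Genes were also raised together: 72 genes of chromosome 18 from CABLES1 to TCF4 had medians of 0.20 in replicate 1 and 0.17 in replicate 2, with 15 called higher and 0 called lower by limma. Weaker stretches went both ways. On each of the 23 chromosomes searched, the stretch that stood out most in replicate 1 had a median of the same sign in replicate 2, 12 lowered and 11 raised. In both replicates 8 were lowered and 5 raised by over 0.1. Both replicates share the differences of single genes, and this search was not repeated on shuffled gene order. The shared sign alone therefore does not show that neighbours moved together. On chromosome 12, 169 genes from VDR to TSPAN31 had medians of -0.14 and -0.16 (42 lower, 3 higher), and on chromosome 19, 730 genes from TNFSF9 to CENPBD2P had -0.11 and -0.12 (106 lower, 23 higher). The lowered stretches of chromosomes 10, 16 and 22 had medians of -0.12 and -0.12, -0.14 and -0.13, and -0.15 and -0.11. On chromosome 8, 415 genes had -0.08 and -0.09 (62 lower, 9 higher). Raised stretches of chromosomes 2 and 5 had medians of 0.18 and 0.12, and of 0.12 and 0.12. On chromosome X, 152 genes from PLCXD1 to KDM5C had medians of 0.14 in both replicates (31 higher, 9 lower), and a window of 100 genes there reached 0.18, beyond all shuffles. On chromosome 4, 355 genes from CCDC149 to FAT1 had medians of 0.13 and 0.12 (65 higher, 9 lower). Besides the genes named beside the lists, COL2A1 lies in the stretch of chromosome 12, GARIN5A in that of 19, HMGB2 and H2AZ1 in that of 4, HOXD11 in that of 2, MAGEB2 in that of X, and, in weaker stretches, AMOTL2 on 3 and PSMA3 on 14, and each moved the way of its stretch. CKM, on 19, and TIMP1, on X, went against theirs. So did CA1 on 8, KRT10 on 17 and TTN on 2, which were not called (log2 differences 0.91, 0.24 and -0.14).

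Noise of single arrays is argued against as the source of the stretches on chromosomes 7, 13 and 9, because their shift recurred. Together they had a median of -0.284 in the replicates not used to find them (bootstrap interval over genes -0.31 to -0.25). The interval resamples genes as if neighbours were independent, so it does not measure the spread between arrays. A bias that follows gene density is argued against as well: after a fit on local gene density the median was -0.283. The weaker and the raised stretches were not put to these tests. Fewer copies of these stretches in the expanded cells stay open as a possible explanation. Of their genes 82.4% lay below the median of all genes in replicate 2, but this follows from the lowered median and any shift shared by neighbouring genes would give it. DNA was not analysed here, and a bias of base composition that gene density does not follow stays open.

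TXNIP and ARRDC4 both respond to glucose through the same transcription regulator. Glucose in the mice was not analysed here. If glucose supply lowered TXNIP, ARRDC4 was predicted to fall too, and it did (log2 difference -0.899, limma adjusted p = 0.0032). ARRDC4 belongs to the same list and was measured in the same fit that showed the fall of TXNIP. Its fall is therefore no independent check of the prediction. A lower glucose supply in vivo could give both falls, but they do not show it. Other conditions of growth may lower both genes, and the supply itself is unknown.

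MAGEC2, MAGEB2 and PRAME, all cancer-testis genes, rose, PRAME from 366.5 ± 2.76 to 1048 ± 29.5 and MAGEB2 from 26.7 ± 2.0 to 89.3 ± 2.15. MAGEB2 did not pass without in vivo replicate 2 (limma adjusted p = 0.056), and its log2 difference was 0.76 against 1.30 with a pseudocount of 64. A general release of such genes may lie behind this. The other 36 measured members had a median log2 difference of 0.032, and 1 of them, MAGEA6, was called higher. The bootstrap interval of the median, from -0.09 to 0.11, reaches past the bound of 0.1 set to exclude a release, and most of these genes were dim (median in vivo signal 9.15), so these data do not decide.

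CCN2, TGFB2 and TNFRSF12A are among the genes induced by YAP and TEAD, and a wider rise of these targets is a possible explanation. The other 19 targets tested had a median of -0.009 (bootstrap interval -0.15 to 0.20), with 4 called higher (CRIM1, CCN1, AMOTL2 and AJUBA) and 1 lower (LATS2). LATS2 lies in the lowered stretch of chromosome 13, so its fall may belong to that stretch, and it did not pass without in vitro replicate 1, in vitro replicate 2 or in vivo replicate 1 (limma adjusted p = 0.0716, 0.0702 and 0.0611). AJUBA did not pass without any 1 array (0.11 to 0.138) or with no filter on low values (0.0591). The interval holds both a rise and a fall, so these data do not decide here either.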
